A study of Homo sapiens with 17 samples.

How the data were processed

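Gene expression was measured on 17 Affymetrix arrays in human breast cell lines. Per the labels, cells were seeded for 24 h and treated for 48 h, total RNA was extracted with Trizol, and biotinylated cRNA was prepared with the GeneChip WT PLUS kit. The deposited values are log2 signals of 24351 probe sets per array. The summarisation, background correction and normalization that the authors used are not given in the sources used here. Quartiles over the genes used differ between arrays, which does not show how the values were normalized. The values were used as deposited. Array data carry no counting depth, and the number of arrays limits the precision.

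Groups were taken from the sample titles. In MDA-MB-231 they were Maraviroc IC20, Maraviroc IC50, DZH_2 IC20, DZH_2 IC50, DMSO and ethanol, with 2 arrays each, and untreated cells with 1 array. In MCF10 they were DZH_2 IC20, DZH_2 IC50, DMSO and untreated cells, with 1 array each. For the 4 MCF10 arrays the titles and descriptions name MCF10 while the cell line field names MDA-MB-231; the titles were followed. Marker genes show that these arrays differ from the MDA-MB-231 arrays, but several epithelial markers are near the negative controls in them, so the identity of the line stays in doubt. IC20 and IC50 are the concentrations that inhibit by 20% and 50%; the concentrations themselves are not given in the sources used here. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

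Of the probe sets, 17709 were paired with exactly 1 gene symbol by Entrez identifier, 2903 were controls and 3739 had no gene listed. For 20 genes with several probe sets the one with the highest mean over the 17 arrays was used (in 12 of them the probe sets differed in sign in at least 1 comparison), which left 17687 genes. The genome build of the array design is not given in the sources used here, so no coordinates are given. No filter on low signal was applied in the main comparisons; a gene is described as near the negative controls where its group mean lay below the 75th percentile of the negative control probe sets.

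The 12 arrays of the 6 replicated MDA-MB-231 groups were fitted together with limma 3.58.1 (lmFit, contrasts.fit, eBayes; R 4.3.3, the data.table package at 1.17.8) on group means, with 6 residual degrees of freedom and 1 estimate of the spread per gene. Tests were 2-sided, with Benjamini-Hochberg adjustment over the 17687 genes and a threshold of adjusted p under 0.05. Each compound was set against its own solvent (ethanol for Maraviroc, DMSO for DZH_2), the doses of each compound were compared, the compounds were compared at matched inhibitory concentration by the difference of their differences from solvent, and the solvents were compared. Log2 differences are between means of 2 arrays per group. Their standard error (±) comes from the 1 spread per gene that limma estimated over the 12 arrays. It can therefore be smaller or larger than the spread of the groups compared. For HMOX1 the SD between replicates was 1.81 for Maraviroc IC50 and 0.34 for ethanol. The step was tested on simulated data with 200 planted genes in 20 runs, for DZH_2 IC50 against DMSO over 17687 genes. Of genes planted at a log2 difference of 1, 16.5% were recovered, with 94.8% at 2 and 99.7% at 3. False calls were 5.48% of the calls. The simulated arrays were independent, with 1 spread per gene in every group. In the data the SD between replicates was 0.546 for Maraviroc IC50 and 0.277 to 0.366 in the other groups. These rates may therefore not hold for the data.

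A set of 36 gene lists with 913 genes (787 measured) was fixed in advance and tested with camera at its preset correlation of 0.01, with adjustment over the lists of a comparison. Beside each call stand the count of members past the threshold over all genes, the count adjusted over the list alone, and the adjusted p with an estimated correlation. No list call of any comparison held with an estimated correlation, apart from the ribosomal protein list of ethanol against DMSO. Overlaps of comparisons that share a solvent were set against 100 simulated data sets with unchanged groups.

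Groups of 1 array were described by values only. In MCF10, genes were counted where both doses differed from DMSO by at least 1 on the log2 scale in 1 direction, and the median of each list was placed among 10000 random lists of the same size matched on mean signal.

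The genes named were chosen by a rule: for each compound against its solvent, the 8 largest rises and the 8 largest falls past the threshold with both treated arrays beyond both solvent arrays (or the 4 smallest p where fewer than 4 genes passed); for the other tests the 4 largest each way; for each list discussed, up to 4 members with the smallest p; and for MCF10 the 8 highest and the 8 lowest. A gene named in 1 comparison could be given in any other. A further gene that the rule names in every comparison is not analysed here. The groups, tests, lists, naming rule and a set of alternatives (quantile normalization, median centring, a filter on the dimmest 25% of genes, a trended robust prior, the 4 arrays compared alone, a replicate block, each array left out in turn, all 5 control arrays as 1 control, other thresholds, all probe sets, other MCF10 settings) were fixed before the data were examined. Array weights, removal of the trend on signal level, a fit without the Maraviroc IC50 arrays and the single MCF10 doses were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.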

Results

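The arrays compared breast cells treated with DZH_2, a compound known here only by its code name, or with Maraviroc, a chemokine receptor antagonist used against HIV, with cells given the solvent alone. MDA-MB-231 is a mesenchymal, triple-negative breast cancer line and MCF10 is a non-tumorigenic mammary epithelial line. MDA-MB-231 contributed 13 arrays: 2 each for Maraviroc IC20, Maraviroc IC50, DZH_2 IC20, DZH_2 IC50, DMSO and ethanol, and 1 of untreated cells. MCF10 contributed 4 arrays, 1 each for DZH_2 IC20, DZH_2 IC50, DMSO and untreated cells. Replicates correlated across genes at 0.984 to 0.991 in 5 of the replicated groups and at 0.960 for Maraviroc IC50, where the SD between replicates was 0.546 against 0.277 to 0.366 elsewhere. The 2 Maraviroc IC50 arrays also had a narrower interquartile range of log2 signal (4.05 and 4.07) than the other 11 MDA-MB-231 arrays (4.21 to 4.65), and a lower positive control signal.

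The arrays titled MCF10 differed from those of MDA-MB-231 in marker genes, but the markers did not settle that they are MCF10. In the untreated and DMSO arrays of each line, the basal epithelial genes S100A2, KRT5, ITGB4 and TRIM29 were 8.17, 4.78, 4.45 and 4.38 higher in MCF10 on the log2 scale, and the mesenchymal genes AKAP12, ZEB1 and VIM were -6.02, -5.15 and -1.70 relative to MDA-MB-231. Other markers went the other way: FN1, TGFBI, SPARC and SNAI2 were 7.61, 7.90, 6.13 and 5.04 higher in MCF10, and ITGA6 was -3.98. The epithelial genes CDH1, CLDN1, ESRP1, OVOL1 and EPCAM stood at 4.07, 4.50, 4.86, 4.39 and 5.24 in the arrays titled MCF10, near the negative controls, and the matrix genes DCN, FBLN1 and MMP2 were 5.02, 8.79 and 9.07 higher there. These arrays are called MCF10 below after their titles. KRT5, TRIM29, SPARC, DCN, FBLN1 and MMP2 in MDA-MB-231 and AKAP12 in MCF10 were near the negative controls, so the sizes of these differences depend on the floor. Of 21 basal epithelial markers 8 were higher by at least 1 and 2 lower, and of 20 mesenchymal markers 10 were lower and 6 higher. S100A2 stood at 6.33 on the Maraviroc IC50 arrays and at 6.37 on the ethanol arrays, far below the 14.8 of MCF10 in DMSO.

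Maraviroc at IC50 lowered genes of the cell cycle and raised genes of stress responses in MDA-MB-231. ANLN (Entrez 54443), a scaffold of the contractile ring in cytokinesis, fell most, by a log2 difference of -7.45 ± 0.40, from 13.2 in ethanol to 5.78. The nuclear lamina genes LMNB1 and TMPO fell (-6.84 ± 0.46 and -6.69 ± 0.43), as did RRM2, a subunit of ribonucleotide reductase (-6.79 ± 0.84). Falls of similar size were those of the mitotic genes PRR11 and NUSAP1 (-6.74 ± 0.61 and -6.11 ± 0.42), ABI3BP, which codes for a matrix protein (-7.00 ± 0.93), and the histone gene H2BC14 (-6.97 ± 0.74). HMOX1 (Entrez 3162), the heme oxygenase induced by oxidative stress, rose most, by 6.39 ± 0.60. With it rose the cytokine IL11 (6.04 ± 0.63), the heat shock gene HSPA1A (5.94 ± 0.93), the lipid droplet gene PLIN2 (5.71 ± 0.35), and the autophagy gene GABARAPL1 (5.64 ± 0.32). The others of the 8 largest rises were KLHL21 (5.09 ± 0.32), CDKN1A, the cyclin-dependent kinase inhibitor p21 (4.89 ± 0.57), and MIR22HG (4.63 ± 0.48).

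By limma, 2122 genes rose and 2656 fell, 4778 of 17687, and in 4777 of them both Maraviroc arrays lay beyond both ethanol arrays. The adjusted p of these 16 genes lay between 6.6e-07 and 5.3e-04. The falls of 7 of the 8 lowered genes, all but H2BC14, ended near the negative controls, and HMOX1 and MIR22HG started near them, so these sizes depend on the floor. HSPA1A and H2BC14 have near-identical relatives and are uncertain as single genes. Without ethanol replicate 1 the count was 2995. With the 4 arrays compared alone it was 2399, and with array weights 3218. The main fit gave each gene 1 spread over all groups. The SD between replicates was 0.546 for Maraviroc IC50 and 0.277 to 0.366 in the other groups, so that spread may be too small for Maraviroc IC50. Centring each array on its median moved the median log2 difference of all genes from 0.106 to 0.276 and gave 3018 rises and 2308 falls.

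The lists moved in the same 2 directions, 7 up and 9 down of 36. Of 30 G2/M and mitosis genes 29 fell (median -4.65, 30 adjusted over the list alone), including TPX2 at -5.88 and CCNB2 at -4.72. The G2/M list had adjusted p = 0.18 with an estimated correlation. Of 34 G1/S and DNA replication genes 29 fell (median -3.20, 31 adjusted over the list alone), including RRM1 at -4.91, GINS1 at -4.83, CDC6 at -4.80 and POLA1 at -3.26. CCNB2, GINS1 and POLA1 ended near the negative controls. The G1/S list had adjusted p = 0.23 with an estimated correlation. Of 32 replication-dependent histone genes, a family of near-identical members that is uncertain gene by gene, 21 fell (median -1.93, 25 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation). In the mesenchymal list 10 of 20 members fell and none rose (median -1.38, 11 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation), including CAV1 at -3.89, MSN at -3.50 and QKI at -2.29. In the list of targets of YAP and TEAD 9 of 18 fell and 2 rose (median -1.10, 9 and 2 adjusted over the list alone, adjusted p = 0.20 with an estimated correlation), including CCN2 at -3.21 and PTPN14 at -2.72.

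Of 24 genes of the NRF2 and oxidative stress list, 13 rose and 2 fell (median 1.04, 15 and 2 adjusted over the list alone), including SQSTM1 at 3.85, SRXN1 at 3.01 and FTL at 1.97. Oxidative stress genes had adjusted p = 0.18 with an estimated correlation. Of 32 lysosome genes 13 rose and 1 fell (median 0.73, 15 and 1 adjusted over the list alone), including NPC1 at 3.31 and CLCN7 at 2.97. Lysosome genes had adjusted p = 0.18 with an estimated correlation. Of 31 immediate early and AP-1 genes 14 rose and 2 fell (median 0.63, 14 and 2 adjusted over the list alone), including JUND at 3.30 and JUNB at 3.04. The AP-1 list had adjusted p = 0.20 with an estimated correlation. Of 24 genes of the unfolded protein response 11 rose and 2 fell (median 0.91, 14 and 2 adjusted over the list alone), with SYVN1 at 2.74, MANF at 2.29 and DNAJB9 at 2.28 and the sensor ATF6 at -2.12. Unfolded protein response genes had adjusted p = 0.20 with an estimated correlation. Of 29 genes of the NF-kB list 11 rose and 3 fell (median 0.49, 11 and 3 adjusted over the list alone), including CXCL8 at 3.51, RELB at 3.15 and the inhibitor NFKBIA at 3.03. NF-kB genes had adjusted p = 0.36 with an estimated correlation. Of 27 autophagy genes 9 rose and 2 fell (median 0.50, 10 and 2 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation).

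Shifts also passed in 5 more lists. In the sterol synthesis list 8 of 20 genes rose and 1 fell (median 0.25, 8 and 1 adjusted over the list alone), with INSIG1 at 3.42 and HMGCS1 at 2.27. Sterol genes here had adjusted p = 0.75 with an estimated correlation. Among 9 LXR targets 3 fell and 1 rose (median -1.02, 4 and 1 adjusted over the list alone), with the sterol exporter ABCG1 at -2.69 and SREBF1 at -1.68. LXR genes had adjusted p = 0.20 with an estimated correlation. The cytoskeleton list (median -0.68, 9 of 23 fell and 2 rose, 10 and 2 adjusted over the list alone), the interferon list (median -0.48, 6 of 31 fell and 1 rose, the same counts adjusted over the list alone) and the collagen and matrix list (median -0.35, 7 of 23 fell, 8 adjusted over the list alone) were lower, with adjusted p = 0.37, 0.37 and 0.20 with an estimated correlation. Without Maraviroc IC50 replicate 2, 9 lists passed in place of 16. The sterol, autophagy, cytoskeleton, interferon, YAP and TEAD, LXR and matrix lists missed the threshold (adjusted p = 0.503, 0.118, 0.243, 0.201, 0.0588, 0.0588 and 0.078). Without Maraviroc IC50 replicate 1 the NF-kB, LXR and matrix lists missed it (0.0585, 0.0634 and 0.0513). It was missed without ethanol replicate 1 by the sterol list (0.176), and without ethanol replicate 2 by the interferon, LXR and matrix lists (0.131, 0.0683 and 0.0648). Quantile normalization left the LXR list at 0.052.

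**Figure D1:**
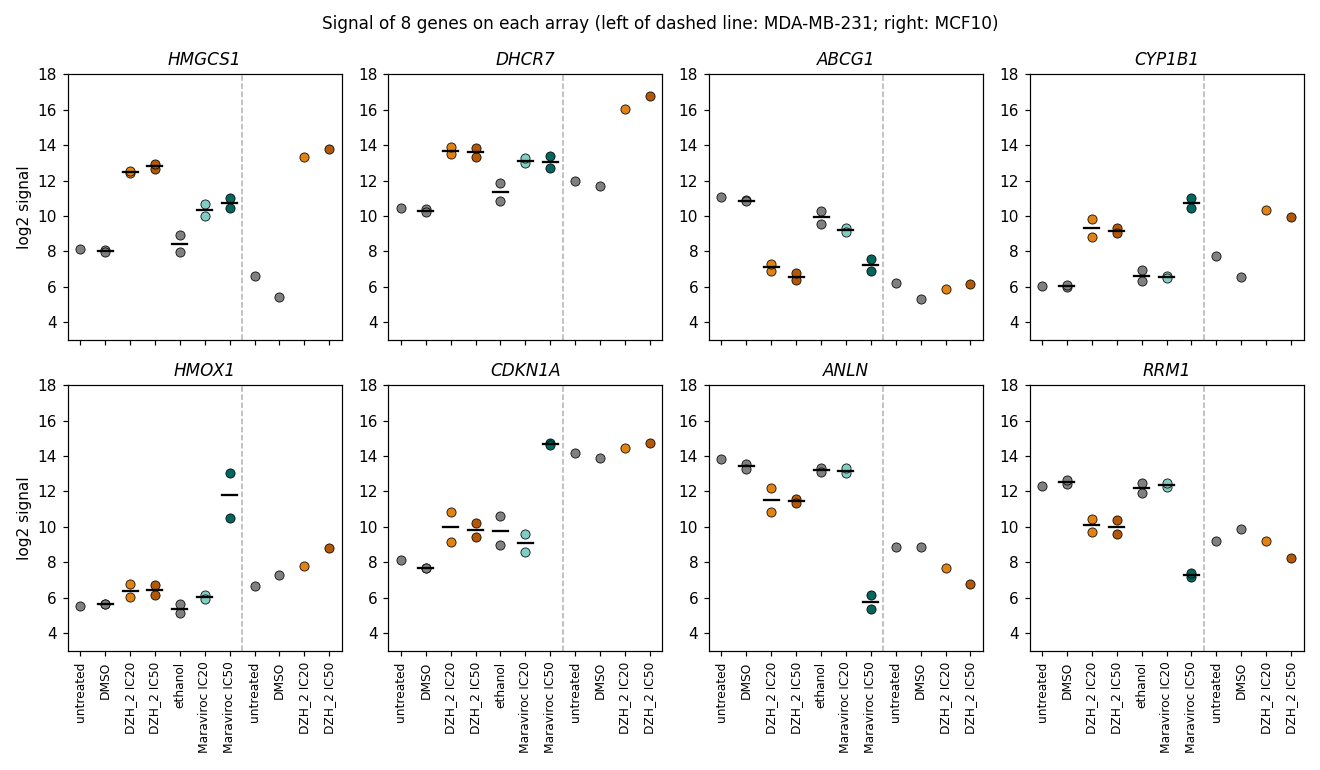
Log2 signal of 8 genes (vertical axes) on each of the 17 arrays, grouped by treatment (horizontal axes); points are arrays, horizontal bars are means of 2 arrays, and the dashed line parts MDA-MB-231 from MCF10. HMGCS1 was 4.76 above DMSO and ABCG1 -4.28 below it at DZH_2 IC50 in MDA-MB-231, while ANLN was -7.45 relative to ethanol at Maraviroc IC50.

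Maraviroc at IC20 passed no single gene against ethanol: limma gave 0 genes, 309 at an unadjusted p under 0.05 where chance gives 884. A count below chance does not show that the groups are alike. The spread per gene was shared with the wider Maraviroc IC50 arrays, although a fit without those arrays also called 0 genes. The deviations of same-numbered replicates of Maraviroc IC20 and ethanol correlated at 0.251, and no paired test was run. The smallest p values belonged to the sterol synthesis genes HMGCS1 (1.89 ± 0.35) and DHCR7 (1.77 ± 0.36) and to the cystatin genes CST4 (-2.38 ± 0.42) and CST1 (-3.32 ± 0.64), all with an adjusted p of 1. HMGCS1 passed against all 5 control arrays (2.12) and CST1 with the 4 arrays compared alone (-3.32), 1 gene each. The cystatin genes are near-identical relatives, uncertain as single genes, and were near the negative controls after treatment. Among the lists 4 were called up and 4 down. The sterol synthesis list had the smallest p, with 19 of 20 members higher (median 0.77, 6 up adjusted over the list alone, 0 over all genes, adjusted p = 0.17 with an estimated correlation), with CYP51A1 at 1.99 ± 0.51 and ACAT2 at 1.52 ± 0.32. The sterol exporters ABCA1 and ABCG1 stood at 1.44 ± 0.35 and -0.70 ± 0.32. Against the DMSO and untreated arrays they stood at -0.27 and -1.72, so the direction of ABCA1 depends on the control.

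The other calls at this dose were small shifts with 0 members past the threshold over all genes or adjusted over the list alone. Medians were 0.42 for the ATF4 amino acid response, 0.25 for targets of YAP and TEAD and 0.15 for ribosomal proteins (adjusted p = 0.83, 0.32 and 0.23 with an estimated correlation). They were -0.30 for G1/S genes, -0.24 for collagens and matrix, -0.19 for the list of epithelial-mesenchymal transition and invasion, and -0.17 for mesenchymal markers (adjusted p = 0.83, 0.17, 0.64 and 0.17 with an estimated correlation). Without Maraviroc IC20 replicate 1, 2 lists passed, and of these 8 the sterol list alone kept its call. Without ethanol replicate 2 the ATF4 list turned to -0.25 and the transition, matrix, mesenchymal, ribosomal protein and YAP and TEAD lists missed the threshold (adjusted p = 0.57, 0.141, 0.122, 0.0935 and 0.12). Without Maraviroc IC20 replicate 2 the matrix and ribosomal protein lists missed it (0.0743 and 0.0716), and without ethanol replicate 1 the G1/S and ribosomal protein lists (0.0879 and 0.146).

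The step from Maraviroc IC20 to IC50 was as large as that from ethanol to IC50. HSPA1A, HMOX1, IL11 and CDKN1A rose most (6.45 ± 0.93, 5.73 ± 0.60, 5.70 ± 0.63 and 5.59 ± 0.57) and ANLN, ABI3BP, PRR11 and TMPO fell most (-7.38 ± 0.40, -7.02 ± 0.93, -6.95 ± 0.61 and -6.77 ± 0.43), each ending near the negative controls. G2/M genes fell in 29 of 30 cases (median -4.66, 29 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation) and targets of YAP and TEAD in 10 of 18 with 1 rise (median -1.60, 12 and 2 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation). In all 2109 genes rose and 2610 fell by limma, and 7 lists were up and 7 down. The count of 4719 was 2662 without Maraviroc IC20 replicate 1, 3011 without Maraviroc IC20 replicate 2 and 2632 with the 4 arrays alone, and median centring gave 2907 rises and 2234 falls. Across genes the differences from ethanol at the Maraviroc doses correlated at 0.163, where unchanged groups sharing those controls gave 0.50, and their covariance was 0.0506 against 0.0572 simulated.

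DZH_2 raised sterol synthesis genes in MDA-MB-231 at both doses and lowered the sterol exporters. HMGCS1 (Entrez 3157), which makes the HMG-CoA of the mevalonate pathway, rose by 4.47 ± 0.35 at IC20 (22.1-fold) and by 4.76 ± 0.35 at IC50 (27.1-fold) against DMSO. MSMO1 and DHCR7, later enzymes of the pathway, rose by 3.39 ± 0.63 and 3.40 ± 0.36 at IC20 and by 3.50 ± 0.63 and 3.32 ± 0.36 at IC50. INSIG1, a sterol-regulated brake on the pathway, rose by 2.88 ± 0.40 and 3.27 ± 0.40. ABCG1 (Entrez 9619) was at -3.77 ± 0.32 and -4.28 ± 0.32, the largest fall at each dose, and ABCA1 was at -2.19 ± 0.35 and -2.43 ± 0.35, ending near the negative controls, so its size depends on the floor. The lipase gene LIPG, near the negative controls in DMSO, rose by 4.08 ± 0.53 and 3.79 ± 0.53, and the transporter gene SLC37A2 by 2.93 ± 0.40 and 3.31 ± 0.40.

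The cytochrome genes CYP1B1 and CYP1A1, targets of the aryl hydrocarbon receptor, also rose, by 3.27 ± 0.35 and 3.22 ± 0.49 at IC20 and by 3.12 ± 0.35 and 3.09 ± 0.49 at IC50. The DNA repair gene XRCC2 was at -2.56 ± 0.42 and -3.32 ± 0.42, and ANKRD36C, which has close paralogs and is uncertain, at -2.73 ± 0.47 and -3.53 ± 0.47. The IC20 set further held MCM8 (-2.66 ± 0.39), the proliferation marker MKI67 (-2.51 ± 0.47), FAM111B (-2.50 ± 0.44), DEPDC1 (-2.43 ± 0.43) and DIAPH3 (-2.42 ± 0.48). The IC50 set held the chromatin remodeller HELLS (-3.37 ± 0.65), the primase PRIM1 (-3.24 ± 0.41), DTL (-3.08 ± 0.46), the centriole kinase PLK4 (-2.93 ± 0.41) and the helicase subunit MCM6 (-2.89 ± 0.43). FAM111B at IC20, and XRCC2 and PLK4 at IC50, ended near the negative controls.

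By limma, 77 genes rose and 77 fell at IC20, and 103 rose and 174 fell at IC50, all by at least 2-fold and with both treated arrays beyond both DMSO arrays. Over the 16 named genes of each dose the smallest adjusted p by limma was 2.4e-04 at IC20, for HMGCS1. At IC50 it was 7.6e-05, for HMGCS1 and ABCG1 alike. These counts rest on every array: the IC20 count of 154 was 131 without DZH_2 IC20 replicate 1, with 72 of the same genes, and 15 without DZH_2 IC20 replicate 2. It was 5 without DMSO replicate 1 (ABCG1, DHCR7, GABARAPL1, HMGCS1 and LIPG) and 2 without DMSO replicate 2 (ABCG1 and HMGCS1). The IC50 count of 277 was 22 without either DZH_2 IC50 replicate 1 or replicate 2, 3 without DMSO replicate 1 (ABCG1, HMGCS1 and LIPG) and 2 without DMSO replicate 2 (ABCG1 and HMGCS1). Of the 16 named genes at each dose HMGCS1 and ABCG1 were the 2 that kept their call throughout. In the other direction, a fit without the 2 widely spread Maraviroc IC50 arrays called 495 genes at IC20 and 837 at IC50, with all 154 and all 277 among them. Array weights called 488 and 942, the 4 arrays alone 244 and 817, and all 5 control arrays 419 and 635. Quantile normalization gave 113 rises and 109 falls at IC50, and removal of the trend on level 105 and 112.

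The sterol synthesis list rose at both doses: 10 of 20 members at IC20 and 13 at IC50, with medians of 1.72 and 1.82 (18 adjusted over the list alone at each dose, adjusted p = 0.063 and 0.089 with an estimated correlation). HSD17B7 was at 2.17 ± 0.31 at IC20 and MVD at 2.02 ± 0.28 at IC50. The fatty acid synthesis list was also higher, with 4 of 15 members rising at IC20 and 3 rising and 1 falling at IC50 (medians 0.98 and 0.74, 8 up and 1 down adjusted over the list alone at each dose, adjusted p = 0.072 and 0.18 with an estimated correlation). ACSS2 was at 2.80 and 2.78, FASN at 2.59 and 2.79 and FADS2 at 1.61 and 1.48, while SREBF1, which codes for a regulator of these genes and is itself an LXR target, was at -1.28 (adjusted p = 0.0551) and -1.36. In the LXR list 2 of 9 members fell at IC20 and 3 at IC50 (medians -0.14 and -0.56, 3 adjusted over the list alone at each dose, adjusted p = 0.072 and 0.089 with an estimated correlation). Of 10 targets of the aryl hydrocarbon receptor 3 rose at IC20 and 4 at IC50 (medians 0.49 and 0.62, 5 adjusted over the list alone at each dose, adjusted p = 0.072 and 0.089 with an estimated correlation), with TIPARP at 1.61 and 1.47.

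Cell cycle lists were lower at both doses of DZH_2. Of 34 G1/S genes 5 fell at IC20 and 10 at IC50 (medians -1.85 and -1.79, 28 and 29 adjusted over the list alone, adjusted p = 0.17 and 0.21 with an estimated correlation), with RRM1 at -2.41 and -2.53 and POLA1 at -1.70 and -2.06. Of 30 G2/M genes 4 fell at each dose (medians -1.21 and -1.02, 20 and 16 adjusted over the list alone, adjusted p = 0.16 and 0.26 with an estimated correlation), with TPX2 at -1.96 and -1.78 and ANLN at -1.93 and -1.97. Proteasome genes had medians of -0.28 and -0.48, with PSMD14 falling at both doses (-1.38 and -1.30) and PSMD1 at IC50 (-1.39), 1 and 2 genes in all by either adjustment. Proteasome genes had adjusted p = 0.39 and 0.26 with an estimated correlation.

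Stress and inflammatory lists were higher. Of 24 NRF2 genes 3 rose at IC20 and 5 at IC50 (medians 0.77 and 0.54, 7 and 8 adjusted over the list alone, adjusted p = 0.063 and 0.089 with an estimated correlation), with SQSTM1 at 2.19 and 2.44 and FTL at 1.35 and 1.27. Of 32 lysosome genes 3 and 4 rose (medians 0.51 and 0.47, 7 adjusted over the list alone at each dose, adjusted p = 0.063 and 0.089 with an estimated correlation), with the protease CTSD at 2.67 and 2.61. Of 31 immediate early genes 2 rose at each dose, JUNB at 1.83 and 1.91 and JUND at 1.95 and 1.69 (medians 0.68 and 0.51, 4 up at IC20, 5 up and 1 down at IC50 adjusted over the list alone, adjusted p = 0.072 and 0.18 with an estimated correlation). Of 29 NF-kB genes 2 rose at IC20, RELB at 1.76 and NFKBIA at 1.62, and 4 at IC50, with IL6 at 2.35 and IL1B at 2.17 (medians 0.28 and 0.57, 5 and 8 adjusted over the list alone, adjusted p = 0.16 and 0.14 with an estimated correlation). Of 27 autophagy genes 2 rose at each dose, including GABARAPL1 at 2.40 and 2.19 (medians 0.35 and 0.21, 5 adjusted over the list alone at each dose, adjusted p = 0.16 and 0.43 with an estimated correlation).

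Among the remaining calls for DZH_2, the metallothionein list was higher (medians 0.64 and 0.72) and the ATF4 amino acid (-0.56 and -0.89), histone (-0.42 and -0.57) and spliceosome lists (-0.42 and -0.67) lower, with 0 members past the threshold over all genes. Adjusted over the list alone, 1 spliceosome gene was up and 3 down at IC20 and 3 down at IC50, and 0 of the other 3 lists. With an estimated correlation the adjusted p = 0.61, 0.80, 0.61 and 0.63 at IC20 and 0.63, 0.63, 0.43 and 0.43 at IC50. At IC20 alone the hypoxia list was called up (median 0.25, 1 of 29 rose, 3 adjusted over the list alone, adjusted p = 0.62 with an estimated correlation), and at IC50 alone the ribosome biogenesis list down (median -0.43, 0 of 22 by either adjustment, adjusted p = 0.64 with an estimated correlation). At IC20 the calls lost were ATF4 and hypoxia without DZH_2 IC20 replicate 1 (ATF4 turned to a median of 0.15; hypoxia 0.0803), metallothionein, histone and spliceosome without DZH_2 IC20 replicate 2 (0.183, 0.326 and 0.703). Without DMSO replicate 1 they were ATF4 and spliceosome (0.261 and 0.286). At IC50 without DZH_2 IC50 replicate 1 it was ATF4 (0.158). Without DZH_2 IC50 replicate 2 they were autophagy, metallothionein and histone (0.351, 0.438 and 0.109). The others were ribosome biogenesis without DMSO replicate 1 (0.0991), and autophagy and metallothionein without DMSO replicate 2 (0.0902 and 0.0545).

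The doses of DZH_2 gave closely related changes in MDA-MB-231. Of the genes called, 61 rose and 62 fell at both doses, where independent lists of these sizes would share 0.448 and 0.758 and unchanged groups against the same DMSO arrays shared 0.02 calls. Across genes the differences correlated at 0.807 (0.50 in the simulation), with a covariance of 0.226 against 0.0572. With 2 DMSO arrays a split would leave 1 to each dose and was not made, so part of the excess in shared calls may come from the shared controls. Shared controls add the same covariance with or without real effects, and the covariance seen was above the simulated one. Between IC50 and IC20 limma called 0 genes, 721 at an unadjusted p under 0.05 where chance gives 884. The deviations of same-numbered replicates of the 2 doses correlated at 0.301 and no paired test was run. A count below chance therefore does not show that the doses act alike. The smallest p values belonged to NPIPB15, NPIPB9, NPIPB6 and NPIPB8 (-1.53 ± 0.25, -1.57 ± 0.28, -1.28 ± 0.26 and -1.34 ± 0.29; adjusted p 0.834 to 0.999), a family of near-identical genes that is uncertain. Of 5 small list calls (leukocyte markers up at 0.25; unfolded protein response, LXR targets, ribosomal proteins and ribosome biogenesis down at -0.28, -0.28, -0.20 and -0.22; 0 members by either adjustment), 0 were left after quantile normalization, and with an estimated correlation the adjusted p = 0.37, 0.60, 0.37, 0.37 and 0.75. The count of lists was 11 without DZH_2 IC20 replicate 1 and 3 without DZH_2 IC50 replicate 2.

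**Figure D2:**
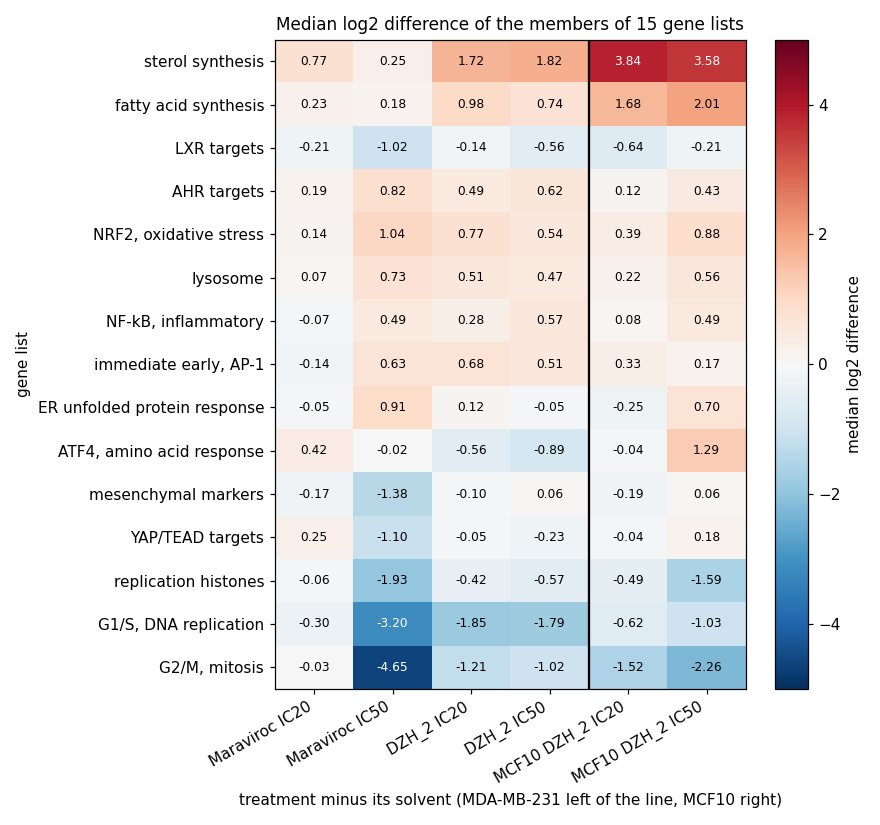
Median log2 difference from solvent (color, and number in each cell) of the members of 15 gene lists (vertical axis) for each treatment (horizontal axis); the black line parts MDA-MB-231 from MCF10. The sterol synthesis median was 1.82 at DZH_2 IC50 in MDA-MB-231 and 3.58 in MCF10, and the G2/M median was -4.65 at Maraviroc IC50.

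At IC50 the genes that differed most between the compounds included cell cycle genes, measured as the DZH_2 difference from DMSO minus the Maraviroc difference from ethanol. PRR11, FOXM1, TMPO and ANLN were 6.12 ± 0.87, 5.91 ± 0.64, 5.50 ± 0.61 and 5.48 ± 0.56 higher for DZH_2 than for Maraviroc. With DZH_2 itself ANLN passed (-1.97), and TMPO, PRR11 and FOXM1 did not (-1.19, -0.62 and -0.10). HMOX1, IL11, PLIN2 and PMEPA1 were lower for DZH_2 (-5.61 ± 0.84, -5.02 ± 0.89, -4.29 ± 0.50 and -4.05 ± 0.59). PRR11, TMPO and ANLN after Maraviroc and HMOX1 in the solvents were near the negative controls, so these sizes depend on the floor. G2/M genes were higher for DZH_2 in 23 of 30 cases (median 3.55, 29 adjusted over the list alone, adjusted p = 0.22 with an estimated correlation). Sterol synthesis genes were higher in 7 of 20 (median 1.08, 10 adjusted over the list alone, adjusted p = 0.41 with an estimated correlation), with HMGCS1 at 2.49 ± 0.49. The sterol median of ethanol against DMSO, 0.49, makes up part of this difference. Mesenchymal genes were higher in 5 of 20 (median 1.39, 9 adjusted over the list alone, adjusted p = 0.076 with an estimated correlation). Genes of the unfolded protein response were lower for DZH_2 in 5 of 24 (median -0.75, 7 down and 1 up adjusted over the list alone, adjusted p = 0.22 with an estimated correlation).

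By limma 711 genes were higher and 380 lower for DZH_2 at IC50, and 10 lists were up and 5 down. The count of 1091 moved with each array left out: 1981 and 1811 without Maraviroc IC50 replicate 1 or 2, 696 and 524 without DZH_2 IC50 replicate 1 or 2, and 508 and 448 without DMSO replicate 1 or 2. It was 524 and 612 without ethanol replicate 1 or 2. PRR11, FOXM1, TMPO, ANLN, HMOX1, IL11, PLIN2 and PMEPA1 passed in all of these. Median centring gave 616 higher and 524 lower and moved the median of all genes to -0.150; removal of the trend on level gave 546 and 471. The compounds also shared calls at IC50, with no array in common: 71 genes rose and 148 fell with both, where independent lists would share 12.4 and 26.1, and 2 went in opposite directions where 36.3 would. Across genes the 2 sets of differences correlated at 0.549; genes are not independent replicates.

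At IC20 no gene passed the test of the difference between the compounds: limma gave 0 genes, 1273 at an unadjusted p under 0.05. The smallest p values were those of CYP1B1 (3.36 ± 0.50, 95% interval 2.28 to 4.44), ABCG1 (-3.07 ± 0.45, -4.05 to -2.08) and ABCA1 (-3.62 ± 0.49, -4.69 to -2.55), each with an adjusted p of 0.095, and ACSS2 (2.85 ± 0.51, 1.76 to 3.95; 0.313). These genes were chosen for their small p, so their intervals were bound to leave out 0. ABCA1 was at -1.80 in ethanol relative to DMSO, which makes up part of its difference: the treated groups differed by 1.82, and after DZH_2 it was near the negative controls. A p that misses the threshold does not show that the compounds act alike. Lists were called up in 9 cases and down in 6, with sterol synthesis at 0.90 (3 members adjusted over the list alone, 0 over all genes, adjusted p = 0.28 with an estimated correlation) and G2/M at -1.27 (10 adjusted over the list alone, adjusted p = 0.28 with an estimated correlation). The sterol list was itself 0.49 higher in ethanol than in DMSO, which makes up part of the 0.90. Without DZH_2 IC20 replicate 1 the count of genes was 1, ABCA1, and without the Maraviroc IC50 arrays it was 4, ABCA1, ABCG1, CYP1B1 and CYP1A1. Across genes the differences of the compounds at IC20 correlated at 0.0228.

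Ethanol and DMSO passed no gene against each other: limma gave 0 genes, 1352 at an unadjusted p under 0.05 where chance gives 884, with the smallest adjusted p of 0.511. The 4 genes with the smallest p were MSMP (5.40 ± 0.92), MIR99AHG (-1.43 ± 0.27), CYB5R4 (-1.57 ± 0.28) and CCDC14 (-1.74 ± 0.33). Ribosomal protein genes were lower in ethanol (median -0.48, 0 of 17 by either adjustment, adjusted p = 0.048 with an estimated correlation). In all 9 lists were called up and 3 down, among them histones at 0.73, sterol synthesis at 0.49 and hypoxia at 0.48 up and ATF4 at -0.63 down, each with 0 members by either adjustment (adjusted p = 0.43, 0.43, 0.43 and 0.73 with an estimated correlation). Without ethanol replicate 2, 5 lists passed; ATF4 turned to 0.03 and the sterol and hypoxia lists missed the threshold (0.201 each), and without DMSO replicate 1 ATF4 missed it (0.0861). Against the single untreated array 45 genes were higher and 73 lower by at least 1 in DMSO, and 97 and 177 in ethanol, where ABCA1 stood at -1.52 and ABCG1 at -1.17; these differences have no replicate check.

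In MCF10 sterol synthesis genes were higher with DZH_2 at both doses; there was 1 array per group, so these differences have no replicate check and no test. HMGCS1 was 7.89 higher than in DMSO at IC20 and 8.35 at IC50, IDI1 7.10 and 6.94, CYP51A1 6.70 and 6.80 and SC5D 5.35 and 4.95; these 4 were near the negative controls in DMSO, so the sizes depend on the floor. MSMO1 was higher by 4.99 and 4.98, DHCR7 by 4.34 and 5.10, the desaturase SCD by 4.33 and 4.86 and MVD by 4.08 and 4.84. The lowest genes were the sodium channel subunits SCNN1G (-7.95 and -7.44) and SCNN1B (-4.34 and -4.25), the histone gene H2BC14 (-5.92 and -6.38), the mitotic genes CDC20 (-4.72 and -5.58), FOXM1 (-4.39 and -4.98), PTTG1 (-3.23 and -4.52) and FAM83D (-3.37 and -4.24), and the retinol carrier RBP4 (-3.77 and -3.99). SCNN1G and RBP4 at both doses and SCNN1B at IC20 ended near the negative controls. Against the untreated array HMGCS1 was 6.74 and 7.20 higher, IDI1 5.21 and 5.04, and H2BC14 and RBP4 were at -5.03 and -5.49 and at -4.41 and -4.62.

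Of 20 sterol synthesis genes 17 were higher by at least 1 at both doses in MCF10 (medians 3.84 and 3.58, above all 10000 random lists matched on signal), and of 15 fatty acid synthesis genes 9 were (1.68 and 2.01, likewise). G2/M medians were -1.52 and -2.26, with 21 of 30 lower at both doses, and G1/S medians -0.62 and -1.03, with 10 of 34 lower, each below the 1st percentile. DMSO relative to untreated cells lay at percentile 99.3 for G2/M and 70.4 for G1/S. A single array can thus reach an extreme percentile without DZH_2. CYP1B1 was 3.76 and 3.39 higher than in DMSO and 2.58 and 2.21 higher than in untreated cells. Of the 10 targets of the aryl hydrocarbon receptor it was the only 1 higher by at least 1 at both doses. ALDH3A1 was lower (-1.81 and -1.40), and 8 were neither. That list had medians of 0.12 and 0.43, at percentiles 75.7 and 94.9 of random lists. Against untreated cells the medians were 3.80 and 3.47 for sterol synthesis, -1 and -1.68 for G2/M and -0.41 and -0.88 for G1/S. In all, 800 genes were higher and 864 lower at both doses by at least 1. Both doses were set against the same single DMSO array, so error in that array alone gives agreement between them, and single arrays allow no value for no change. DMSO and untreated cells, a single pair of arrays, differed by at least 1 in either direction in 1464 genes. By the same count of a single pair, IC20 differed from DMSO in 4324 genes and IC50 in 3221. The IC20 array stood apart in its controls, with the highest background signal of the 17 arrays, 6.09, and the lowest positive control signal, 11.02.

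The genes DZH_2 changed in MDA-MB-231 were compared with the same genes in the arrays titled MCF10. If the titles hold, this sets a cancer line against a non-tumorigenic line; the markers leave that in doubt. Of the 103 genes raised at IC50 in MDA-MB-231, 87 were higher in MCF10 at IC50, 53 of them by at least 1, against 50.7% of all genes. Of the 174 lowered genes 106 were lower in MCF10, 41 of them by at least 1, against 49.3% of all genes. At IC20, 61 of 77 raised genes were higher and 43 of 77 lowered genes were lower. Over all genes the differences correlated at 0.0456 at IC20 and 0.141 at IC50, as a description of these arrays. The difference between the lines was not tested.

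**Figure D3:**
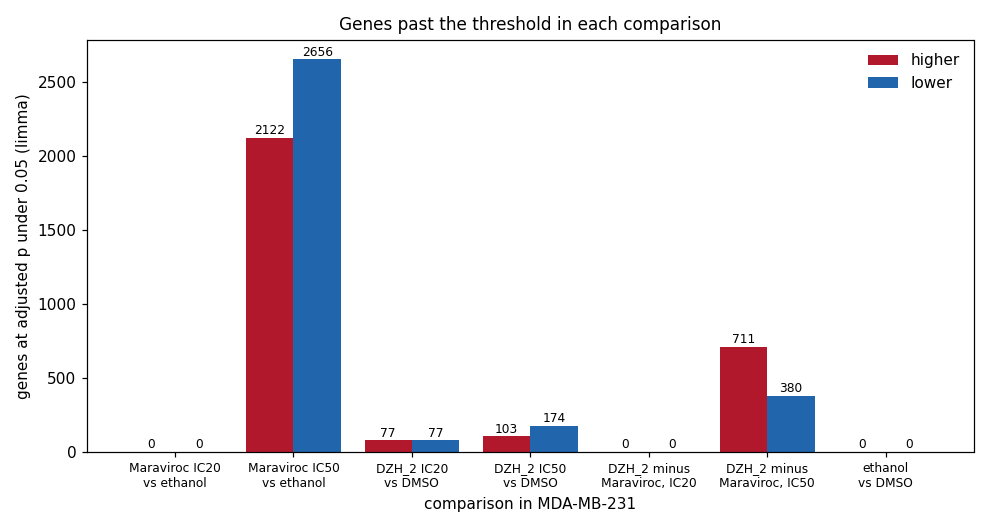
Number of genes past an adjusted p of 0.05 by limma (vertical axis) in each comparison of MDA-MB-231 groups (horizontal axis), higher in red and lower in blue. Maraviroc IC50 gave 2122 and 2656 genes, DZH_2 IC50 103 and 174, and Maraviroc IC20 0. With array weights Maraviroc IC50 gave 3218 genes in all and DZH_2 IC50 942.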

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

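The tests of a response shared with DZH_2, of low DMSO arrays, of low cell sterol, of a mild form of the DZH_2 response and of low ethanol arrays, and the step of 0.5 used for control probes, were chosen after the result they measure had been seen. Each SE below is the standard error of the mean over the genes of a set, printed beside their median. These genes share the same arrays, so the SE does not measure the spread between arrays.

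Maraviroc at IC50 changed 4778 genes on 2 arrays that also had a narrow signal range and high hybridization controls. A compressed signal range is argued against as the whole cause: with each array's trend on signal level removed, the G2/M median stayed at -4.33 (SE 0.207 over the members; -4.65 before). For the loss of 1 array's quality, 77.7% and 80.2% of the genes passed without 1 or the other of the 2 arrays. Most of these calls thus did not rest on 1 array alone. The genes had been chosen by their calls with both arrays, which favours passing again. The test therefore cannot decide whether 1 array was of lower quality, and that stays open. A response shared in part with DZH_2 goes with the signs, in comparisons that share no array. Of the 277 genes DZH_2 changed at IC50, 95.3% had the same sign with Maraviroc IC50, against 66.6% of all genes. Of the genes Maraviroc IC50 changed, 79.3% had the same sign with DZH_2 IC50. A quality loss common to both arrays and specific to some transcripts stays open, because it is confounded with the treatment. Hybridization controls of these 2 arrays (12.7 on each) lay within the range of the MCF10 arrays (12.47 to 12.94). The other 11 MDA-MB-231 arrays were lower (11.14 to 11.95). ERCC and negative controls behaved likewise, and background controls did not. The cause of this likeness was not tested and cannot be told apart from the treatment.

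DZH_2 raised sterol synthesis genes and lowered ABCA1 and ABCG1 in MDA-MB-231. DMSO arrays that read low for sterol genes are argued against: against the ethanol and untreated arrays the sterol median at IC50 was 1.56 (SE 0.254; 1.82 against DMSO). A compressed signal range is argued against by a median of 1.89 (SE 0.251) with the trend on level removed. A candidate explanation is low sterol in the cells, which would raise these genes and lower LXR targets, but in MCF10 the 8 measured LXR targets other than SREBF1 lay at percentile 30.5 of random lists at 1 dose and 1.55 at the other, so this explanation cannot be told apart from others: the percentiles fall on both sides of the bound of 5 and the low-signal members of a short list decide little. A direct action on the regulators of these genes was not tested.

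The sterol list was also higher with Maraviroc at IC20, where no gene passed the test. Ethanol arrays that read low for sterol genes are argued against, because they read higher. Relative to the single untreated array the sterol median was 0.41 in ethanol and -0.08 in DMSO. Against the DMSO and untreated arrays the sterol median with Maraviroc IC20 was 1.39 (SE 0.151, and 0.77 against ethanol). That value holds the solvent difference as well as the compound, so it was bound to exceed 0.77 and is no separate evidence. A mild form of the DZH_2 response is left open: the 103 genes DZH_2 IC50 raised had a median of 0.25 (SE 0.0516) with Maraviroc IC20, above all random lists matched on level but short of the 0.3 set for the test. Without the sterol list, 90 of those genes had a median of 0.188 and 66 were higher, while of the 174 genes DZH_2 IC50 lowered 96 were lower (median -0.04), and over all genes the differences correlated at 0.0383. The cases cannot be told apart, because the median lies between the bounds, and ABCA1, lowered by DZH_2, was 1.44 above ethanol but at -0.27 against the DMSO and untreated arrays, where ABCG1 was at -1.72.

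Of 425 named genes, 6 lay at least 0.5 from DMSO one way on all 4 DZH_2 arrays of MDA-MB-231 and the other way at both MCF10 doses; 0 of 36 lists did, and the difference between the lines was not tested for any of them. ABCG1 was at a mean of -4.02 in MDA-MB-231 and at 0.53 and 0.82 in MCF10, where its DMSO signal of 5.34 was near the negative controls. The cystatin gene CST4, with close paralogs and a signal of 3.34 in MCF10 DMSO, was at -1.72 against 0.61 and 1.55. The phosphatase gene DUSP1 was at 1.74 against -1.45 and -1.07. The glycyl-tRNA synthetase gene GARS1 was at -1.96 against 0.81 and 2.10. The serine synthesis gene PSAT1 was at -2.70 against 1.41 and 2.75. Over the 4 DZH_2 arrays of MDA-MB-231, PSAT1 ran from -4.32 to -0.96 and GARS1 from -2.86 to -1.21. The SD of PSAT1 and GARS1 between replicates was 1.80 and 1.47 in ethanol and 0.04 and 0.13 in DMSO. The proteasome gene PSMD14 was at -1.34 against 0.92 and 0.86. ABCG1 and PSMD14 passed by limma in MDA-MB-231 at DZH_2 IC50, and CST4, DUSP1, GARS1 and PSAT1 did not (adjusted p = 0.0905, 0.241, 0.235 and 0.216). The opposite direction of ABCG1 and CST4 rests on the single MCF10 DMSO array: against untreated MCF10 cells ABCG1 was at -0.33 and -0.03 and CST4 at -0.27 and 0.66. GARS1 was at 0.19 and 1.48 against untreated cells, and DUSP1, PSAT1 and PSMD14 kept their direction by at least 0.5 at both doses.

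Among 30 pairs of a control probe class and a treated group, 2 lay at least 0.5 above the highest control array of their line. The hybridization controls of the Maraviroc IC50 arrays were 1.01 above it (12.7 against 11.7). The poly-A controls of the MCF10 DZH_2 IC20 array were 0.689 above it (10.01 against 9.32).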

How the results depend on the processing

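Array weights, removal of the trend on level, the fit without the Maraviroc IC50 arrays and the single MCF10 doses were chosen after the data had been seen, and genes are named for small counts after their values had been seen. The direction of every named gene's difference held wherever it was called: over all settings 11545 values kept their side of the threshold and 0 reversed, 773 were no longer past it, 237 were newly past it, and 34 values that passed in neither setting changed sign. For lists 784 calls were kept, 239 lost and 4 turned. The 16 genes named for Maraviroc IC50 and the 8 for the compounds at IC50 passed in every setting; of the 16 for each dose of DZH_2, all passed in every setting that leaves out no array and 2, HMGCS1 and ABCG1, in all. A scale other than log2 did not apply.

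Counts of genes moved as follows, and the cause was not tested where none is given. With the 4 arrays compared alone, which changes both the degrees of freedom and the arrays that set the spread, Maraviroc IC20 gave 1, Maraviroc IC50 2399, DZH_2 IC20 244, DZH_2 IC50 817 and the Maraviroc step 2632. With all 5 control arrays Maraviroc IC20 gave 1, DZH_2 IC20 419 and DZH_2 IC50 635. With array weights DZH_2 IC20 gave 488, DZH_2 IC50 942 and the compounds at IC20 3 (ABCA1, ABCG1 and CYP1B1). Without the Maraviroc IC50 arrays these were 495, 837 and 4. Counts that involve the Maraviroc IC50 arrays fell with array weights: 3218 for Maraviroc IC50, 3406 for the Maraviroc step and 920 for the compounds at IC50. An unadjusted p under 0.05 with a 2-fold change gave 67 for Maraviroc IC20, 926 and 1177 for DZH_2 IC20 and IC50, 84 for the DZH_2 step, 995 and 3027 for the compounds at IC20 and IC50 and 378 for the solvents. In MCF10 1.5-fold in place of 2-fold gave 4012 genes in place of 1664, IC50 alone 3221 and IC20 alone 4324.

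Leaving out each array in turn gave 0 genes for Maraviroc IC20, the DZH_2 step and the solvents, 2995 to 5080 for Maraviroc IC50, 2 to 131 for DZH_2 IC20, 2 to 22 for DZH_2 IC50, 2662 to 5062 for the Maraviroc step, 0 to 1 for the compounds at IC20 and 448 to 1981 at IC50. It gave 2 to 9 lists for Maraviroc IC20, 9 to 17 for Maraviroc IC50, 15 to 17 and 14 to 17 for DZH_2 IC20 and IC50, 11 to 16 for the Maraviroc step, 3 to 11 for the DZH_2 step, 11 to 19 and 12 to 16 for the compounds at IC20 and IC50, and 5 to 13 for the solvents. A left-out arm then holds 1 array, assumed to vary like the other groups. The ATF4 median ran from -0.255 (without ethanol replicate 2) to 1.15 for Maraviroc IC20, from -1.35 to 0.146 (without DZH_2 IC20 replicate 1) for DZH_2 IC20 and from -1.30 to 0.0342 (without ethanol replicate 2) for the solvents. The G2/M median ran from -0.0369 (without DMSO replicate 2) to 0.465 for the solvents. The cause of these turns was not tested. An estimated correlation left 0 lists in each of 8 comparisons and 1 for the solvents, and quantile normalization left 0 for the DZH_2 step.

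With the replicate number as a block, the counts were 4821 for Maraviroc IC50, 204 and 347 for DZH_2 IC20 and IC50, 4776 for the Maraviroc step, 1172 for the compounds at IC50, 2 for the compounds at IC20 (CYP1B1 and DIAPH3) and 0 for the other 3. The numbers do not pair the samples across all groups: 3 of 15 correlations of same-numbered deviations were over 0.1 (-0.149 to 0.301). All 3 lay within a compound and its solvent: DZH_2 IC20 with IC50 (0.301), Maraviroc IC20 with ethanol (0.251) and Maraviroc IC50 with ethanol (0.122). The other pairs of this kind were lower: Maraviroc IC20 with IC50 (-0.003), DZH_2 IC20 with DMSO (0.069) and DZH_2 IC50 with DMSO (-0.034). The block was common to all groups, so pairing within a compound and its solvent was not tested and stays open. Signals near the negative controls limit the size of a fall that the arrays can show.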

Other observations

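The counts of genes that lay at least 0.5 from DMSO on every DZH_2 array of both lines were chosen after the data had been seen.

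In MCF10 several groups were higher with DZH_2 beyond those of lipid synthesis and the cell cycle, as values of 1 array per dose. The interferon list had medians of 0.62 and 0.83 at IC20 and IC50, and the NRF2 list 0.39 and 0.88. Each list lay above the 99th percentile of random lists at both doses. In the interferon list IFIT1 was at 2.63 and 3.39. Its signal was near the negative controls both in DMSO (3.41) and at IC20 (6.05), so the IC20 value is uncertain. Heat shock genes had medians of 0.29 and 1.01, with the chaperone gene HSPA1A, uncertain for its near-identical relative, at 0.37 and 2.86. The ATF4 amino acid list stood at -0.04 at IC20 and 1.29 at IC50, where the cystine transporter gene SLC7A11 was at 0.78 and 4.48 (1.81 and 5.51 against untreated cells); in MDA-MB-231 the same list had medians of -0.56 and -0.89. The scavenging chemokine receptor gene ACKR3 was at -3.40 and -4.07. The basal marker S100A2 was at -3.54 and -4.04.

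The LXR list had medians of -0.64 and -0.21 in MCF10, at percentiles 2.55 and 22.5 of random lists, and of -0.33 and 0.01 against untreated cells. Over all genes, 374 lay at least 0.5 from DMSO in the same direction on the 4 DZH_2 arrays of MDA-MB-231 and both of MCF10, and 176 in opposite directions.

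With Maraviroc at IC50, several genes outside the largest changes passed in MDA-MB-231 by limma: the stress cytokine gene GDF15 rose by 4.12 ± 0.66, the stress regulator DDIT3 by 4.04 ± 0.61, the hexokinase gene HK2 by 3.84 ± 0.27 and CYP1B1 by 4.09 ± 0.35, while the kinase gene PLK2 was at -5.19 ± 0.28. CYP1B1 thus rose with both compounds at IC50 in MDA-MB-231, and with DZH_2 at IC50 in MCF10 it was 3.39 above DMSO and 2.21 above untreated cells. DDIT3 started and PLK2 ended near the negative controls. Of 15 chemokine receptors and ligands 1 passed, CCL7, which was near the negative controls in ethanol, so no size is given, and the list was not called.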
